A study of Mus musculus with 10 samples.

How the data were processed

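Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on mononucleosomes from fractionated mouse spermatocytes and round spermatids, per the labels' protocols. Each immunoprecipitation used about 100 ug of mononucleosomes and 5 ug of a rabbit antibody against H4K5ac, H4K5bu, H4K8ac or H4K8bu, that is, histone H4 acetylated (ac) or butyrylated (bu) at lysine 5 (K5) or lysine 8 (K8). The series had 10 samples: 1 library for each of the 4 marks in each of the 2 stages, and 1 input library per stage, sequenced from nucleosomes without immunoprecipitation. The groups were taken from the sample titles. With 1 library per group, no test between groups was possible and no p-value between groups was computed.

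The submitters' processing notes, per the labels, named CASAVA 1.8.2, Bowtie2 2.2.5, deepTools 1.5.11, SICER and the mouse genome build mm9. The settings given to these tools, the version of SICER, the treatment of duplicate reads and the treatment of reads that map to several places were not given in the sources used here. The deposited files were 8 lists of islands, 1 per immunoprecipitated library, with no header. Their columns held the position, the count of ChIP reads and the count of input reads deposited for each island, a p-value, a fold and a q-value. Neither input library had a list of its own, and input reads entered only as the deposited counts in the islands. The deposited fold was the ratio of ChIP to input reads times 1 constant per list, which stands for the ratio of the library sizes. Of all islands, 4 with 0 input reads departed from this rule. Every deposited q-value was below 0.01, island edges lay on a grid of 200 bp, and neighbouring islands of a list were at least 800 bp apart. The largest coordinate on chromosome 1 was 197128600, which fits mm9 and lies beyond the end of chromosome 1 in the next build.

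All positions are given in mm9, counted from 1. The gene table at hand was for another build (GRCm38.p6), so islands were not assigned to genes, promoters, exons or introns, and the planned comparison of promoters and genes is not analysed here; the gene lists chosen for it were not used. Regions are named by their coordinates.

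Depth was read from the lists as the ChIP reads that fell inside islands, 4768412 to 9230541 per library. Of the library sizes, only the ratio of input to ChIP, the constant of each list, was used. The 95% intervals were exact (Clopper-Pearson) for a share, exact conditional binomial for a ratio of shares or a fold, and from order statistics for a median. The intervals of shares, ratios and folds cover counting error only. That of a median reflects the spread between regions, taken as independent, and not a shift common to a whole list. None covers variation between animals or immunoprecipitations. Reads without molecular identifiers are not independent molecules, and neighbouring islands are not independent, so the true uncertainty is wider.

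Overlap was counted as the percent of islands in a list that shared at least 1 bp with any island of the other list. Chance overlap was the mean of 100 placements of each list's islands at random positions of their own chromosome (seed 11). The Jaccard index was the number of bases shared by a pair of lists divided by the bases in either. All 8 lists were merged into 59989 regions with a median length of 3600 bp. A mark covered a region when at least 1 of its islands lay in it, and the ChIP and input reads of these islands were summed to give the region's fold, scaled by the list's constant. Such a fold covers the called islands alone, so it depends on how far each list extended them. A region without an island of a mark is uncalled for it, which is not the same as a measured absence. The share of X was the percent of a list's islands on X, and the 19 autosomes, compared in the same way, served as the yardstick for its change. The butyryl to acetyl balance was the log2 ratio of the butyryl and the acetyl fold of a region at the same residue. Because the lists of a stage shared 1 input library, correlations of fold within a stage were set beside those of simulated unchanged libraries that share an input.

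Regions named in the text followed a rule set before the data were examined. For each mark it took the 2 regions per stage with the most ChIP reads among those called in that stage only, and the 2 per direction with the largest ratio of folds among regions with at least 100 ChIP reads in both. For each stage it took the 5 regions with the highest mean log2 fold over the 4 marks, and for each residue and stage the 2 regions per direction with the most extreme balance, again with at least 100 reads in each list. The Y chromosome and mitochondrial DNA were left out of this rule. The text gives the regions that it needs.

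The alternatives set before the data were examined were the upper 50% of each list by fold, lists shortened to the same length (28031 islands) by fold, overlap of at least 50% of the shorter island, removal of the 1% of islands with the densest input, removal of islands under 600 bp, shares of X by covered length and by ChIP reads, and balances from reads per kb scaled to equal totals. Added after the data were seen were X without its 5 Mb window from 120 Mb, islands with at least 100 ChIP reads, removal of the 10% of islands with the densest input (with the density on X as deposited or doubled, since males have 1 copy), regions with islands of matched length (within 1.2 times), and regions without regard to H4K8ac. The code was tested on simulated lists of 40000 sites with known overlap, X share and balance. The largest error was 0.438 percentage points for the 4 acetyl and butyryl overlaps, 0.034 (log2) for the X ratios of the 4 marks and 0.0019 (log2) for the balances of the 2 residues. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.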

Results

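Acetylation and butyrylation of histone H4 at lysines 5 and 8 were mapped in 2 stages of male germ cell development, spermatocytes, which are in meiosis, and round spermatids, the haploid cells that follow. Butyrylation places a longer acyl chain than acetylation on the same lysine, so at 1 lysine of 1 histone the modifications exclude each other. The data were 8 lists of enriched islands, 1 library per mark and stage, each called against the input library of its stage. No group had a replicate, so none of the differences between libraries could be set against the spread of replicates. Intervals are 95% and cover counting error only or, for a median, the spread between regions.

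All 4 marks were found at many places in both stages, H4K5ac most strongly over input. In spermatocytes the lists held 44291 islands for H4K5ac, 38074 for H4K5bu, 35791 for H4K8ac and 41306 for H4K8bu. In round spermatids they held 37865, 41319, 28031 and 34807 islands in the same order. The islands of spermatocytes covered 151 Mb for H4K5ac, 155 Mb for H4K5bu, 117 Mb for H4K8ac and 161 Mb for H4K8bu. Those of round spermatids covered 186, 185, 116 and 185 Mb. ChIP reads inside islands numbered 8187368, 8054706, 5587630 and 9230541 in spermatocytes and 8435692, 9227752, 4768412 and 8367957 in round spermatids. These counts reflect enrichment and list length as well as depth: by the ratio of input to ChIP library size, H4K5ac had the smallest ChIP library of each stage (1.69 and 2.12), and in round spermatids H4K8ac the largest (1.42). Pooled over the islands of a list, the fold over input was highest for H4K5ac in both stages, at 6.22 in spermatocytes and 5.30 in round spermatids. It was lowest for H4K8ac in both stages, at 4.05 and 3.03, and H4K5bu (4.16 and 3.98) and H4K8bu (4.69 and 3.75) lay between. By the median island, H4K5ac was again highest, but in spermatocytes H4K5bu (4.04) was lower than H4K8ac (4.15).

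The first comparison asked whether acetylation and butyrylation of a lysine occupy the same places. They did for most islands. At K5 in spermatocytes, 92.0% of butyryl islands (91.7 to 92.3) overlapped an acetyl island, against 12.3% for randomly placed islands, and 78.1% of acetyl islands (77.7 to 78.5) overlapped a butyryl island. At K5 in round spermatids the values were 85.7% (85.3 to 86.0; random 13.1%) and 89.9% (89.6 to 90.2). At K8, 93.4% of acetyl islands in spermatocytes (93.2 to 93.7) and 95.9% in round spermatids (95.7 to 96.2) overlapped a butyryl island. The reverse overlap at K8 was lower, 77.6% (77.2 to 78.0) and 71.6% (71.1 to 72.1) of butyryl islands. The lower value of a pair always belonged to the longer list, and with lists of equal length the percents at K8 lay closer together, at 83.4 and 86.2 in spermatocytes and 78.9 and 85.9 in round spermatids.

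Islands of K5 and K8 with the same acyl group also overlapped for the most part. Of H4K8ac islands, 94.9% (94.7 to 95.2) in spermatocytes and 97.1% (96.9 to 97.3) in round spermatids overlapped an H4K5ac island. Of H4K8bu islands, 81.4% (81.0 to 81.8) and 93.8% (93.5 to 94.0) overlapped an H4K5bu island. The reverse overlap was 73.7% (73.3 to 74.2) and 66.1% (65.6 to 66.6) of H4K5ac islands, and 90.0% (89.7 to 90.3) and 81.4% (81.1 to 81.8) of H4K5bu islands. Counted in bases, the 12 pairs of lists of the same stage had a median Jaccard index of 0.607 (0.555 to 0.704 over the pairs). Lists of the same mark from the other stage had a median of 0.463 over 4 pairs, and lists of another mark from the other stage 0.448 over 12 pairs. The lists thus grouped by stage more than by residue or acyl group, but each stage also had its own input library, shared by its 4 lists.

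**Figure D1:**
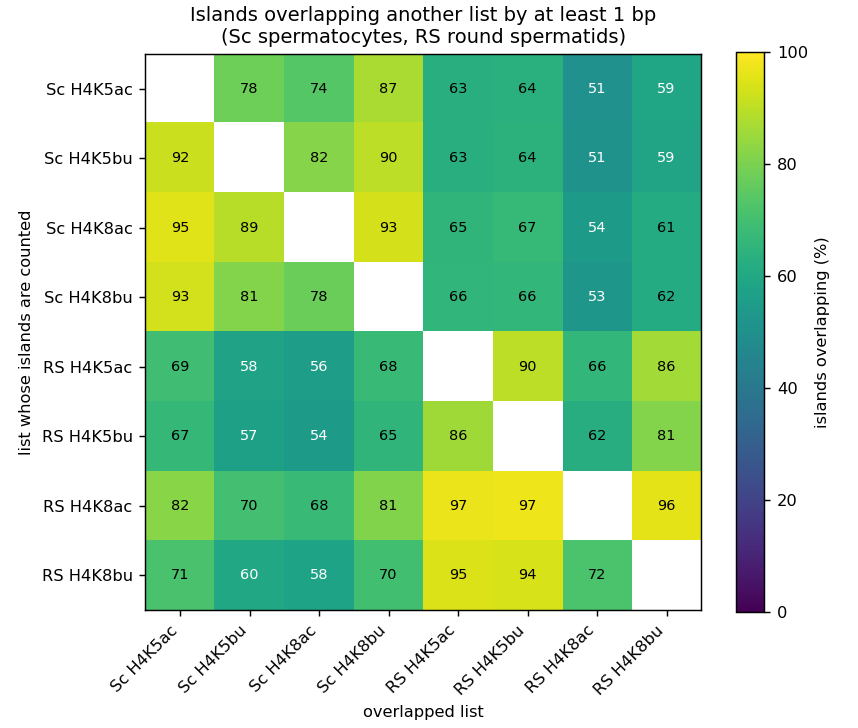
Percent of the islands of each list (rows) that shared at least 1 bp with an island of another list (columns), for spermatocytes (Sc) and round spermatids (RS). Pairs within a stage, in the upper left and lower right blocks, reached 97.4%, and the lowest value between stages was 50.7%, for spermatocyte H4K5ac islands against round spermatid H4K8ac.

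The next comparison asked where all 4 marks met. Regions with all 4 marks were the largest class in both stages, 27529 in spermatocytes (59.7% of the regions with any mark) and 23180 in round spermatids (54.7%). They were also the most enriched, but calling alone can give this order, as a stronger place passes the threshold in more lists. In spermatocytes the median H4K5ac fold was 3.38 in regions with H4K5ac alone and 7.001 in regions with all 4. In round spermatids it was 3.25 and 5.46. Each of the other marks had the same order, with medians of 2.33 to 2.57 for single marks and 4.44 to 5.23 for all 4 in spermatocytes, and 1.84 to 2.48 and 3.15 to 4.15 in round spermatids. Regions with all 4 marks were also longer, with a median of 5400 bp against 2400 bp for single marks in spermatocytes and 6600 bp against 2400 bp in round spermatids. The most frequent incomplete set in round spermatids lacked H4K8ac alone, 6506 regions or 15.3%, where spermatocytes had 2751 or 5.96%; the H4K8ac list was the shortest of each stage.

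**Figure D2:**
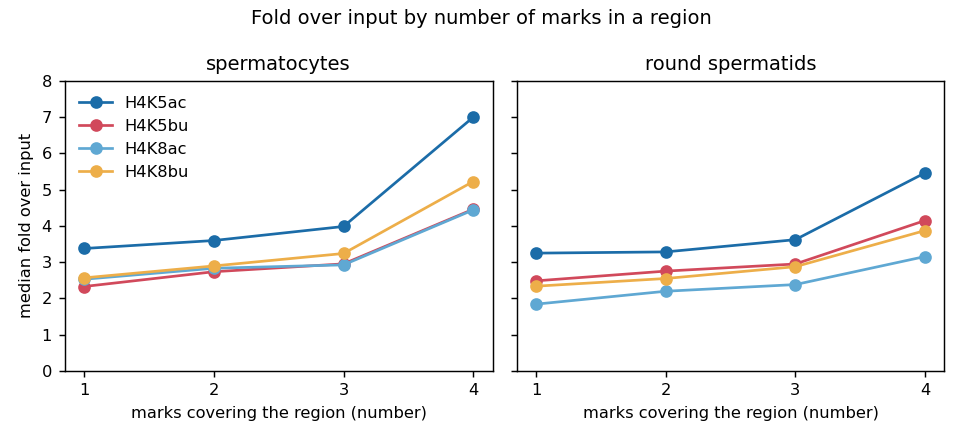
Median fold over input of each mark (vertical axis) in regions covered by 1, 2, 3 or 4 marks (horizontal axis), in spermatocytes on the left and round spermatids on the right. For all 4 marks and both stages the median was highest in regions with 4 marks, as for H4K5ac with 7.001 in spermatocytes and 5.46 in round spermatids.

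The regions with the highest mean fold over the 4 marks had been fixed by rule as 5 per stage. In spermatocytes the first lay on chromosome 10 from 20670001 to 20675400, with a fold of 45.9 (27.0 to 84.8) for H4K5ac, 20.1 (12.5 to 34.4) for H4K5bu, 21.3 (12.2 to 40.7) for H4K8ac and 31.6 (18.6 to 58.3) for H4K8bu. Its folds in round spermatids were 10.1, 7.55, 5.03 and 6.39, with 40 input reads in its H4K5ac islands against 14 in spermatocytes. The others lay on chromosome 2 from 31425801 to 31431400, chromosome 6 from 88466201 to 88470800, X from 97622001 to 97631600 and chromosome 11 from 44282001 to 44286400, and their H4K5ac fold was 44.2, 30.5, 34.0 and 27.5. All 5 were called for all 4 marks in round spermatids too, with an H4K5ac fold of 7.53 to 11.5. These regions were chosen for a high spermatocyte fold over few reads of a shared input, so some fall was built in. Their intervals are not adjusted for this choice. In round spermatids the first region lay on chromosome 18 from 18519001 to 18524200. Its folds were 14.9 (10.6 to 21.3), 11.02 (8.03 to 15.5), 7.13 (4.96 to 10.5) and 9.54 (6.97 to 13.3), against 3.99 (2.78 to 5.81), 2.93 (1.92 to 4.57), 2.15 (1.46 to 3.19) and 2.65 (1.93 to 3.68) in spermatocytes. The remaining regions of round spermatids were on chromosome 1 from 99057201 to 99064200, X from 133652001 to 133659600, chromosome 2 from 136081601 to 136086400 and chromosome 15 from 66408001 to 66412000. Their H4K5ac fold was 13.0 to 16.4 in round spermatids and 10.7 to 16.7 in spermatocytes.

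For each mark, a large part of the regions was called in 1 stage only. Without replicates, how much repeat lists of the same stage would differ is not known. Below, new, gained and lost describe where regions were called, not a measured gain or loss of a mark. Of regions marked in spermatocytes, 61.7% for H4K5ac, 62.3% for H4K5bu, 52.9% for H4K8ac and 60.01% for H4K8bu were also marked in round spermatids. In the lists as deposited, H4K5bu had more new than lost regions, 16258 called in round spermatids alone and 12944 in spermatocytes alone. The other marks had fewer new than lost regions, 11005 and 15554 for H4K5ac, 7672 and 15070 for H4K8ac and 9978 and 15138 for H4K8bu. New minus lost regions is the difference in regions called between the stages, so its sign largely follows list length. The upper 50% of each list by fold kept the ratios of list length, so the same directions there add no support. With lists of equal length the numbers of new and lost regions lay closer together. They were 11681 and 11213 for H4K5ac, 11243 and 11025 for H4K5bu, 11056 and 11939 for H4K8ac, and 12008 and 11740 for H4K8bu. Regions marked in 1 stage were weaker than shared ones, as for H4K5ac, with a median fold of 5.00 against 6.35 in spermatocytes and 3.48 against 5.37 in round spermatids. Calling alone can give this order too.

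All 4 marks together were present in both stages in 15655 regions. In 6844 regions spermatocytes had all 4 and round spermatids none, and in 2943 regions the reverse held. Lost regions had a median H4K5ac fold of 5.70 and gained regions one of 3.71. The ratio of gained to lost regions was not stable. Without regard to H4K8ac, 8345 regions lost and 6546 gained the other 3 marks. With lists of equal length, 4917 regions lost and 4427 gained all 4, and in the upper 50% of each list by fold 3046 lost and 2535 gained them.

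Among single regions, 2 on X had large islands of all 4 marks in spermatocytes and none in round spermatids. The region from 16081601 to 16095400 held 925 H4K5ac reads against 84 input reads, a fold of 18.6 (14.9 to 23.5), and folds of 8.72 (7.11 to 10.8) for H4K5bu, 8.97 (7.09 to 11.5) for H4K8ac and 12.6 (10.2 to 15.7) for H4K8bu. The region from 6655801 to 6671800 had folds of 11.4 (9.36 to 14.1), 7.13 (5.96 to 8.58), 8.19 (6.45 to 10.5) and 8.42 (7.05 to 10.1). On chromosome 15, the region from 99928801 to 99945800 had an H4K8ac fold of 4.03 (3.47 to 4.71) in spermatocytes and no H4K8ac island in round spermatids, where its H4K5ac fold was 3.13 (2.46 to 3.99) after 6.11 (5.35 to 7.01). The regions with the most reads among those called in round spermatids alone were of another kind, with very deep input and a fold of 1.14 to 1.801 for the mark that named them. On chromosome 9 from 2999801 to 3038600, at the start of the assembled sequence, 42118 input reads gave a fold of 1.14 (1.12 to 1.16) for H4K5bu, and on chromosome 8 from 19913601 to 20038400, 15253 input reads gave one of 1.27 (1.23 to 1.30) for H4K5ac. Among the regions with the most reads called in spermatocytes alone, 3 also had a low fold over deep input. They lay on chromosome 8 from 19853401 to 19902600, with 3297 input reads and an H4K5ac fold of 1.11 (1.05 to 1.18), on chromosome 13 from 65579201 to 65600400, with 846 input reads and an H4K5bu fold of 1.23 (1.12 to 1.36), and on chromosome 17 from 30589601 to 30620200, with 529 input reads and an H4K8ac fold of 1.4998 (1.33 to 1.69).

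In some regions marked in both stages the folds differed several-fold. Each stage's fold covers its own called islands, so part of such a difference can come from islands of unequal extent, as unequal input reads show. The H4K5bu fold on chromosome 6 from 33379801 to 33385000 was 2.39 (1.79 to 3.21) in spermatocytes and 9.76 (7.44 to 13.0) in round spermatids, and on chromosome 16 from 69795201 to 69805000 it was 2.54 (2.03 to 3.20) and 9.78 (7.56 to 12.8). The H4K5ac fold of these regions was 4.63 and 14.6 on chromosome 6 and 4.40 and 13.5 on chromosome 16. On chromosome 4 from 90764601 to 90769200 the H4K5ac fold was 2.86 (2.07 to 3.98) and 11.7 (8.02 to 17.5), from 105 ChIP reads over 62 input reads and 182 over 33. In the other direction, the H4K5ac fold on chromosome 13 from 65152001 to 65155400 was 20.8 (12.5 to 37.1) in spermatocytes and 2.88 (2.12 to 3.93) in round spermatids. It came from 197 ChIP reads over 16 input reads and from 102 over 75. The 3 other marks there had folds of 8.33 to 12.2 and 2.52 to 3.32. The H4K8bu fold on chromosome 19 from 58333201 to 58337600 was 15.6 (10.4 to 24.5) and 2.19 (1.63 to 2.94), from 330 ChIP reads over 25 input reads and 116 over 81. Over all regions marked in both stages, the log2 fold of the stages had a Pearson correlation across regions, which are not independent replicates, of 0.41 for H4K5ac, 0.41 for H4K5bu, 0.38 for H4K8ac and 0.36 for H4K8bu.

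The X chromosome, whose genes are silenced in meiosis in male germ cells and in part stay repressed afterwards, had few islands in both stages and a larger share of them in round spermatids. For H4K5ac, X held 755 of the islands in spermatocytes, 1.70% (1.59 to 1.83), and 1271 in round spermatids, 3.36% (3.18 to 3.54), which is a ratio of shares of 1.97 (1.798 to 2.16). The ratio was 2.11 (1.90 to 2.36) for H4K5bu, from 476 to 1092 islands, and 1.97 (1.77 to 2.18) for H4K8bu, from 582 to 965. For H4K8ac it was 1.47 (1.29 to 1.69), from 406 to 468 islands. No autosome had a ratio above 1.04 for H4K5ac, 1.06 for H4K5bu, 1.10 for H4K8ac or 1.05 for H4K8bu. Along X, 32 of 34 windows of 5 Mb had more H4K5ac regions in round spermatids, 33 more H4K5bu regions and 29 more H4K8bu regions, but 16 had more and 16 fewer H4K8ac regions.

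The islands called on X in round spermatids, many of them at other places, had a lower median fold than those called in spermatocytes. It was 5.50 after 8.39 for H4K5ac, 4.10 after 6.48 for H4K5bu, 2.92 after 6.36 for H4K8ac and 4.12 after 6.75 for H4K8bu. On autosomes the medians were 4.54 after 5.46, 3.48 after 4.01, 3.10 after 4.12 and 3.497 after 4.38 in the same order. At X regions called in both stages the median change was smaller than between the medians of all X islands, -0.052, -0.14, -0.36 and -0.23 (log2), against -0.24, -0.092, -0.43 and -0.28 over all chromosomes. Of X regions with any change from all 4 marks to none or the reverse, 120 lost and 160 gained all 4, while autosomes had 6722 losses and 2773 gains. Without regard to H4K8ac, 165 X regions lost and 477 gained the other 3 marks, and on autosomes 8178 lost and 6054 gained them. Measured by ChIP reads, the ratio of X shares was 1.26, 1.06, 1.35 and 1.29 for H4K5ac, H4K5bu, H4K8ac and H4K8bu, and for H4K5bu this lay below the highest autosome (1.13). Among islands with at least 100 ChIP reads it was 1.34 (1.15 to 1.56) for H4K5ac, 1.11 (0.944 to 1.31) for H4K5bu and 1.44 (1.24 to 1.66) for H4K8bu, and that of H4K8ac turned to 0.746 (0.592 to 0.935). It also turned in the upper 50% of the H4K8ac lists by fold, to -0.29 on the log2 scale. The X share of input reads in the islands rose too, from 1.18, 1.06, 1.07 and 1.12% to 1.91, 1.52, 2.59 and 1.99%. In round spermatids it lay above the X share of ChIP reads for every mark (1.61, 1.28, 1.49 and 1.61%). In spermatocytes it lay below that share (1.29, 1.21, 1.10 and 1.25%).

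**Figure D3:**
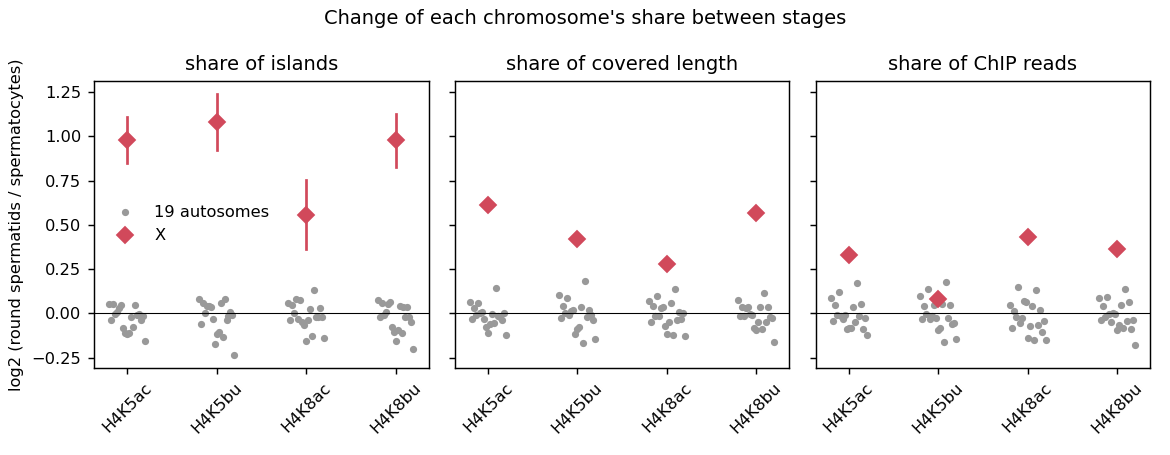
Log2 ratio of each chromosome's share in round spermatids to its share in spermatocytes, for shares of islands, of covered length and of ChIP reads; grey points are the 19 autosomes, red diamonds X, and red bars 95% counting intervals. By islands X lay above all autosomes for the 4 marks (1.97, 2.11, 1.47 and 1.97 as ratios), and by reads H4K5bu lay among them at 1.06.

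For H4K8ac, much of the difference on X lay in 1 place. The 5 Mb window from 120 Mb had 16 H4K8ac regions in spermatocytes and 72 in round spermatids. The 88 round spermatid H4K8ac islands there had a median fold of 1.42 and a median input of 40.0 reads per kb, against 3.33 and 15.0 on the rest of X. Without this window the log2 ratio of X shares was 0.32 in place of 0.56.

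**Figure D4:**
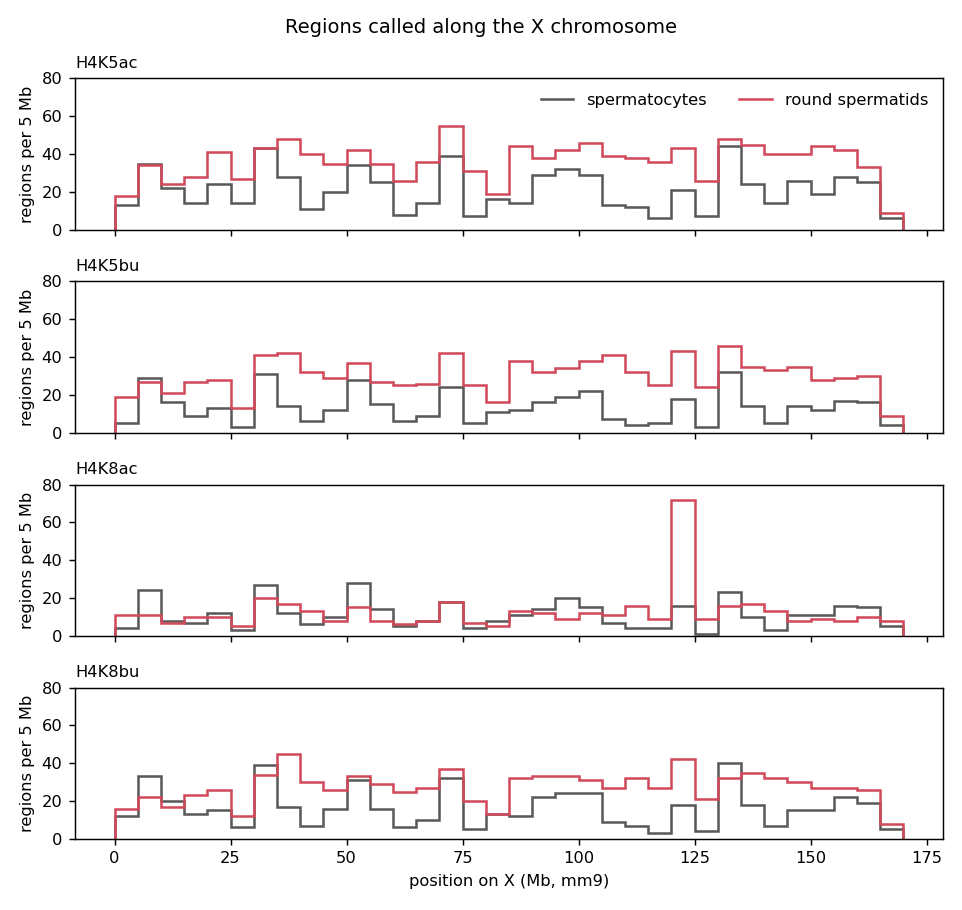
Number of regions per 5 Mb (vertical axis) along X in Mb of mm9 (horizontal axis) for each mark, in spermatocytes (grey) and round spermatids (red). More regions in round spermatids were seen in 32, 33 and 29 of 34 windows for H4K5ac, H4K5bu and H4K8bu, and in 16 for H4K8ac, whose window from 120 Mb reached 72.

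The last comparison asked whether the balance of butyrylation and acetylation at a lysine differed between the stages. At K5 the butyryl to acetyl balance was higher in round spermatids in 76.2% of the 19513 regions with both marks in both stages. Its median was -0.68 (log2) in spermatocytes and -0.39 in round spermatids, and the median change per region 0.27 (0.27 to 0.28). The H4K5ac fold of these regions had a median change of -0.38 and the H4K5bu fold one of -0.063. At K8 the change was smaller, 0.057 (0.051 to 0.064) over 16430 regions, of which 56.0% had a higher balance in round spermatids. The median change of single autosomes ran from 0.24 to 0.33 at K5 and from 0.030 to 0.082 at K8, and X had 0.18 over 220 regions and 0.035 over 106. With reads per kb scaled to equal totals, the change was 0.13 at K5 and turned to -0.13 at K8.

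Acetyl and butyryl folds followed each other across regions of a stage. The Pearson correlation of log2 fold was 0.84 at K5 and 0.83 at K8 in spermatocytes and 0.82 and 0.75 in round spermatids. Simulated unchanged libraries with a shared input gave 0.80, 0.80, 0.74 and 0.71. The covariance was 0.38, 0.34, 0.24 and 0.14, against 0.057, 0.060, 0.038 and 0.033 simulated. The simulation holds only the counting error of the shared input.

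The most extreme balances belonged to regions in which the lists had called islands of unequal extent, as their input reads show. The lowest balance at K5 in spermatocytes lay on chromosome 5 from 145726801 to 145730600, with 177 H4K5ac reads over 7 input reads and 212 H4K5bu reads over 36, which gave folds of 42.7 (20.3 to 108) and 6.99 (4.89 to 10.2). The highest was on chromosome 17 from 59043201 to 59049200, with an H4K5bu fold of 7.42 (4.60 to 12.6) over 20 input reads and an H4K5ac fold of 3.46 (2.62 to 4.61) over 77. At K8 in spermatocytes the highest balance lay on chromosome 10 from 85417401 to 85423200, with 194 H4K8bu reads over 13 and 188 H4K8ac reads over 57. In round spermatids the region on chromosome 6 from 124909401 to 124920400 was among the lowest at both lysines, with 203 H4K5ac reads over 28, 315 H4K5bu reads over 98, 110 H4K8ac reads over 18 and 250 H4K8bu reads over 94.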

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

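The settings with equal list lengths, with the upper 50% of each list by fold and with scaled libraries were set before the data were examined, and the test of weaker acetyl enrichment after the change of the K5 balance, but before its own result, had been seen; the other tests in this part, with the cut of the densest input, were chosen after results on these patterns had been seen, as was the split of the tests on X by mark.

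The number of islands moved in opposite directions between the stages: round spermatids had 1.09 times as many H4K5bu islands as spermatocytes, but 0.855 times as many for H4K5ac, 0.783 times for H4K8ac and 0.843 times for H4K8bu. Covered length did not follow these counts. It was 1.24, 1.19, 0.992 and 1.15 times that of spermatocytes for H4K5ac, H4K5bu, H4K8ac and H4K8bu. The median island was 1.38, 0.94, 1.23 and 1.33 times as wide in the same order. With 1 library per mark and stage the difference between marks was not tested. Mitochondrial DNA, which carries no histones, was called as enriched in 3 butyryl lists and in none of the acetyl lists. Its islands had folds of 1.16 (H4K5bu) and 1.18 (H4K8bu) in spermatocytes and of 1.42 and 1.27 for 2 H4K5bu islands in round spermatids. They were left out of the named regions but stayed in the lists for the other comparisons.

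The share of islands on X was larger in round spermatids. For H4K5ac, H4K5bu and H4K8bu, the log2 ratio of X shares in the deposited lists exceeded that of the highest autosome by 0.92, 0.996 and 0.90. The excess was at least 0.56 in lists of equal length and 0.37 in the upper 50% by fold. This argues against unequal list lengths and islands of low fold as the whole cause. Both cuts rank islands by fold, which a relatively lower X input, left open below, would raise on X. Their reading on X was set after results had been seen. Without the densest 10% of input, with the density on X doubled for its single copy, the excess was 0.36 for H4K5ac and 0.30 for H4K5bu. With the density as deposited it was 0.87 and 0.93. Dense input may thus account for part of the excess of these marks, but part remained. For H4K8bu it was 0.16 with an interval that includes 0 (0.80 with the density as deposited), where dense input stays open. Among islands with at least 100 ChIP reads the excess was 0.35 for H4K8bu, but -0.072 for H4K5bu, the smaller of the K5 marks. Islands with few reads thus stay open for H4K5ac and H4K5bu, as does a relatively lower X input for all 3 marks. At regions called in both stages, the X to autosome ratio of input in round spermatids was at most 0.849 times that in spermatocytes. This would raise X folds, yet over all islands the ratio was at least 1.16 times that in spermatocytes. For H4K8ac, equal list lengths (0.073) and the single window from 120 Mb (0.18) left intervals that include 0, dense input was not decided (0.046 as deposited, with an interval that includes 0, and -0.76 with the density on X doubled), and weak islands are a candidate explanation, as X fell below the highest autosome among islands with at least 100 reads (-0.69) and in the upper 50% by fold (-0.56). The stage itself stays an untested explanation, as the stages are also separate libraries and inputs.

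The butyryl to acetyl balance at K5 was higher in round spermatids. Weaker acetyl enrichment that compresses strong regions is a candidate explanation, since the change was larger by 0.20 (log2) in the tercile of regions with the highest fold of the K8 marks than in the lowest. At K8 the same comparison ran the other way (0.014 in the highest and 0.098 in the lowest tercile), but there the acetyl and butyryl folds fell almost alike (-0.42 and -0.37), so K8 decides little about acetyl enrichment alone. Scaling of the libraries could not be excluded: with libraries scaled to equal reads in the compared regions the change was 0.13, and such scaling itself moves the median towards 0. The median island width in round spermatids was 1.38 times that in spermatocytes for H4K5ac and 0.94 times for H4K5bu. In the 1216 regions with islands of matched length the K5 change was 0.20, so island extent was not excluded as a part of it. A biological difference between the stages stays open beside these and was not tested.

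The balance of single regions may in part reflect how far islands were extended, as its correlation across regions with the log2 ratio of island lengths was -0.48 to -0.62. Among regions more than 2-fold from the median balance, the percent whose acetyl and butyryl islands differed in length by more than 1.5 times exceeded that of all regions by at least 60.7 percentage points, for each residue and stage. Whether each region keeps a balance of its own between the stages was not decided, with a correlation across regions of at most 0.23 among those with at least 500 reads per library. In regions with islands of matched length it was 0.29 at K5 (1216 regions) and 0.21 at K8 (587 regions).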

How the results depend on the processing

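The tests of X without its window from 120 Mb, of islands with at least 100 ChIP reads, without the 10% of islands with the densest input, of regions with islands of matched length and of regions without regard to H4K8ac were chosen after the data had been seen. Removal of the 1% of islands with the densest input and removal of islands under 600 bp left all 46 values within their intervals, or counts within 1.5 times. Of the changed values below, the cause was not tested unless stated. Counts fall in shortened lists by construction. Region counts, X shares and balances were not computed for overlap of at least 50%, nor balances for lists of equal length, and the setting for promoters (start site inside an island) was not run for want of an mm9 annotation. By the ratio of input to ChIP library size, depth was lowest for H4K5ac in both stages (1.69 and 2.12). The 1 library per group leaves no replicate to omit.

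Overlap within a stage is given in the order H4K5bu in H4K5ac, H4K8bu in H4K8ac, H4K8ac in H4K5ac and H4K8bu in H4K5bu. In the upper 50% of each list by fold it was 90.5, 75.2, 91.5 and 79.1% in spermatocytes and 79.8, 66.4, 90.7 and 85.9% in round spermatids. With lists of equal length it was 85.4, 83.4, 85.7 and 84.5% in spermatocytes, and 78.9, 84.5 and 83.2% for the last 3 in round spermatids. With overlap of at least 50% of the shorter island it was 91.2, 77.2, 94.5 and 80.9% in spermatocytes and, for the first, the third and the fourth pair, 84.9, 96.7 and 93.3% in round spermatids.

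The percent of spermatocyte islands that overlapped a round spermatid island was 52.2 for H4K5ac, 60.5 for H4K5bu, 46.5 for H4K8ac and 47.5 for H4K8bu in the upper 50% of each list. With lists of equal length it was 58.5 for H4K5ac, 58.8 for H4K5bu and 56.5 for H4K8bu, and with overlap of at least 50% it was 63.6 for H4K5bu, 53.8 for H4K8ac and 61.1 for H4K8bu. In the upper 50% of each list, 13044 regions in spermatocytes and 10352 in round spermatids had all 4 marks, and 3046 lost and 2535 gained all 4. With lists of equal length, 4917 regions lost and 4427 gained all 4, and each mark but H4K8ac had more new than lost regions. In the lists as deposited, 6546 gained the other 3 marks without regard to H4K8ac.

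The log2 ratio of X shares was 0.68 for H4K5ac, 0.58 for H4K5bu and 0.57 for H4K8bu in the upper 50% of each list, and that of H4K8ac turned to -0.29. With lists of equal length it was 0.72 for H4K5ac, 0.31 for H4K8ac and 0.69 for H4K8bu. By covered length it was 0.61, 0.42, 0.28 and 0.57 for H4K5ac, H4K5bu, H4K8ac and H4K8bu, and by ChIP reads 0.33 for H4K5ac, 0.078 for H4K5bu and 0.36 for H4K8bu. Among islands with at least 100 ChIP reads it was 0.42, 0.15 and 0.52 for H4K5ac, H4K5bu and H4K8bu, and that of H4K8ac turned to -0.42. Without the window from 120 Mb that of H4K8ac was 0.32. Without the 10% of islands with the densest input it was 0.19 for H4K8ac; with the density on X doubled for its single copy before that cut it was 0.45, 0.40 and 0.25 for H4K5ac, H4K5bu and H4K8bu, and that of H4K8ac turned to -0.61.

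The change of the butyryl to acetyl balance was 0.33 at K5 and 0.032 at K8 in the upper 50% of each list. With reads per kb scaled to equal totals it was 0.13 at K5 and turned to -0.13 at K8, and in regions with islands of matched length 0.20 and 0.080.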

Other observations

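The Y chromosome, left out of the named regions, also had a larger share of islands in round spermatids, from 31 to 45 islands for H4K5ac, 19 to 40 for H4K5bu, 15 to 37 for H4K8ac and 28 to 42 for H4K8bu. The ratios of shares were 1.70 (1.05 to 2.78), 1.94 (1.10 to 3.55), 3.15 (1.69 to 6.18) and 1.78 (1.08 to 2.98). They varied with the measure: by covered length they were 1.32, 1.27, 4.74 and 1.52, and by ChIP reads 1.52, 1.38, 21.9 and 2.78. For H4K8ac in round spermatids, Y held 0.66% of ChIP reads in 0.15% of covered length, so reads there were denser than in the whole list. In spermatocytes these shares were 0.030% and 0.031%. The fold and input density of Y islands are not given here, so whether dense input underlies these ratios was not tested.

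X regions that had all 4 marks in spermatocytes and none in round spermatids were few (120), with a median H4K5ac fold of 10.2 in spermatocytes, against 5.65 for the 6722 autosomal regions of the same kind. A higher fold on X was not particular to them. In regions with all 4 marks in both stages the spermatocyte median was 9.60 on X and 7.87 on autosomes. Spermatocyte H4K5ac islands had a median of 8.33 input reads per kb on X and 14.1 on autosomes. X regions that gained all 4 marks had a median H4K5ac fold of 4.11 in round spermatids, against 3.69 on autosomes.

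In spermatocytes, 2 places had islands with ChIP reads and 0 input reads. On chromosome 9 from 64948401 to 64949000 there were 51 H4K5ac reads and 40 H4K8bu reads, and on chromosome 16 from 78377201 to 78377800 there were 49 H4K8ac reads and 62 H4K8bu reads. Neither place had an island in a round spermatid list.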
